A study of Mus musculus with 4 samples.

How the data were processed

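RNA was extracted with Trizol from cultured vascular smooth muscle cells, and biotin-labelled cRNA was made from 0.5 ug of total RNA by a standard Affymetrix procedure, per the labels' protocols. The deposited table holds log2 values per probe set for 4 arrays, made with RMA, per the submitters' processing notes; its version and settings are not given in the sources used here. RMA by default corrects the background, makes the arrays' distributions equal and summarises probes by a robust fit, so a shift of most genes in 1 direction would not be seen in such values. In the table the quartiles of the 4 arrays lay close to each other, and values ran from 2.09 to 14.0. Values near the low end hold background as well as signal, so differences of dim probe sets are compressed. No scanner files, scan dates or array batches were used here.

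Probe sets were named from the accession in their identifier, matched without its version to a table of mouse genes (assembly GRCm38.p6, used for names only). Of 1246 probe sets 963 had 1 symbol, which gave 909 genes, 48 of them with more than 1 probe set. The other 283 had none here, 261 of them with UCSC names, and stayed in the tests of probe sets. Identifiers end in s for 237 probe sets, in x for 38 and in a for 91, marks that can stand for probes shared between transcripts or genes. No Affymetrix control probe sets were in the table.

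Groups, replicate numbers and the culture names WT2 and WTA came from the sample titles. A "3w" in the titles was not interpreted. The replicate number marks the same named cell sample in both arms, so the numbers pair the arrays. Same-numbered arrays deviated together from their group means (correlation 0.600 across probe sets). The main fit had no block, as fixed before the data were examined.

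Streptozotocin was compared with control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the deposited log2 values, 2 arrays per group, 2 residual degrees of freedom and 1.68 prior degrees of freedom), with Benjamini-Hochberg adjustment over 1246 probe sets and a threshold of 0.05. The culture difference was the culture term of a fit with treatment and culture. Within each culture the difference of the 2 log2 values was taken with no test, since each arm holds 1 array there. Intervals for SDs and correlations are 95% bootstrap intervals over probe sets from 2000 draws. They take probe sets as independent and hold no spread between arrays or cell samples.

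Lists of genes were written before the data were examined, 30 in all. Symbols were matched to current names, and each gene was taken from its probe set with the highest mean. The 26 lists with at least 5 measured genes were tested with limma's camera with a preset correlation of 0.01 against the other genes on the array, and camera's p was adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Camera asks whether a list's genes differ from the other genes, while fry asks whether they move, on balance, in 1 direction. All list p-values in the text are camera's unless fry is named, and 0 lists passed by camera, by camera with an estimated correlation or by fry. At an unadjusted p under 0.05 the 3 gave 3, 0 and 1 lists. The smallest p adjusted over a list alone was 0.308, so 0 genes passed in that way.

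The genes to be named were set by rule before the data were examined. They were the 12 largest differences in each direction past the threshold, filled up, where fewer passed, with those above the array median (5.86) that went the same way in both cultures. To these came up to 4 members with the largest difference per list, 14 genes named in advance, and the 5 genes with the largest culture difference in each direction, taken among those past the test. Genes outside the rule are said to be so, and 1 gene that the rule names is not reported here.

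The fits were tested on simulated data for the 1246 probe sets, with 200 changed probe sets in each of 50 draws. The streptozotocin fit recovered 3.07% of 1.5-fold, 48.9% of 2-fold and 86.4% of 4-fold changes, with 0.821% false among its calls. With the replicate block the shares were 52.4%, 92.2% and 99.0%, with 5.23% false, and for the culture term 51.7%, 91.6% and 98.8%, with 4.88% false. A shift of the chemokine list by 0.5 was called in 50 of 50 draws, and 1 of 1250 tests of other lists was called. The simulated noise was independent between genes, and streptozotocin changes were equal in both cultures. In the data the estimated correlation within a list reached 0.44 (fucosyltransferases), and the cultures' differences correlated at 0.151. These rates therefore need not hold for the data.

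Alternatives were the replicate block, each array left out in turn, median centring, quantile normalization, a filter on dim probe sets, an intensity trend, a robust fit, other thresholds, 1 probe set per gene or the mean of all, and the other list tests. Added after seeing the data were the culture fit without the treatment term, its versions without each array, a test of probe sets without the suffixes s, x or a, and other normalizations and a dim filter for the comparison of the 2 cultures' differences. Figures were drawn with matplotlib.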

Results

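The data were 4 expression arrays of vascular smooth muscle cells (VSMC), the contractile cells of the artery wall, from wild-type mice. All cells were kept in osteogenic medium, which drives them towards a bone-like state. The cells of 2 arrays also received 0.4 mM streptozotocin, a glucosamine-containing nitrosourea that is toxic to pancreatic beta cells, and the cells of the other 2 did not. Each arm held 1 array of a cell sample named WT2 (replicate 1) and 1 of a cell sample named WTA (replicate 2), called cultures here. The labels do not say whether the names stand for separate animals, so the p-values of the main fit measure only the spread between these samples. In fits that hold the culture or the replicate block, they measure how unlike the 2 cultures' streptozotocin differences were, not a spread between cell samples. The array measured 1246 probe sets, among them those of genes that build, cut or bind sugar chains (glycogenes) and of cytokines and growth factors. The array medians lay between 5.83 and 5.87 on the log2 scale, and the number of arrays limits the precision. The design text asks how glycogene expression responds to streptozotocin while VSMC calcify. It also names Runx2 knockout cells, which are not analysed here.

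The first comparison, streptozotocin against control, asked which of these genes respond to the compound. The largest difference was at Igfbp5, a secreted binding protein of insulin-like growth factors. Its log2 value was 7.68 ± 0.99 with streptozotocin and 10.49 ± 2.21 in control cells (mean ± SD, n = 2 each), a difference of -2.81, with -3.67 in WT2 and -1.95 in WTA. Igf1, a growth factor that such proteins bind, differed by -0.94, with -0.64 in WT2 and -1.23 in WTA. On the other side, Ackr4, a decoy receptor for chemokines, stood at 7.78 ± 1.26 with streptozotocin and 6.16 ± 0.09 in control cells (SD, n = 2 each), a difference of 2.57 in WT2 and 0.67 in WTA. With 1 array left out, the difference ranged from -4.37 to -1.25 for Igfbp5, from -1.80 to -0.067 for Igf1 and from 0.73 to 2.51 for Ackr4. None of these differences passed the test: limma found 0 of 1246 probe sets at an adjusted p under 0.05.

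The 12 largest positive differences were taken among genes with a symbol, above the array median, that went the same way in both cultures. The dimmer Klra2 (1.38) fell outside these limits. So did brighter genes that were not higher in WTA, among them Cxcl13 (1.66), Cxcl14 (1.06), Il33 (0.93) and Wnt4 (0.93). None of the 12 passed the test. Among them, Ccl7 and Ccl8, chemokines that attract monocytes, differed by 1.34 and 0.88, and Il6, a cytokine of acute inflammation, by 1.04. Icam1, an adhesion molecule for leukocytes, differed by 0.84, and Olr1, a scavenger receptor for oxidised low-density lipoprotein, by 0.97. For Olr1 the difference was close in both cultures, 0.91 in WT2 and 1.03 in WTA. For Ccl7 it was 2.24 in WT2 and 0.45 in WTA, and for Icam1 1.55 and 0.12. The WT2 control array stood at 8.52 for Ccl7, below the 10.15 to 10.76 of the other arrays. For Icam1 it stood at 7.73 against 9.28 to 9.93, and for Il6 at 6.16 against 7.56 to 7.94. Their larger differences in WT2 thus go with a low value in 1 control array. A deviation of that array cannot be told from a lower level in untreated WT2 cells. For Olr1 the control array of WTA was the lowest instead, and Ccl8 had its larger difference in WTA (0.61 in WT2, 1.15 in WTA). The same group held Angpt4 (1.03), a ligand of the Tie2 receptor, and Thbd (0.60), a cofactor of thrombin. It also held Cd44 (0.57), the hyaluronan receptor, and 2 glycosaminoglycan enzymes, Csgalnact1 (0.80) of chondroitin sulfate and Hs6st2 (0.64) of heparan sulfate. The direction turned for Icam1, Thbd and Hs6st2 when 1 array was left out, with ranges of -0.20 to 1.87, -0.27 to 1.48 and -0.14 to 1.41. Leaving out 1 array unbalances the cultures, so such values also hold the culture difference, and within the cultures Hs6st2 differed by 0.65 in WT2 and 0.63 in WTA.

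The 12 largest negative differences were chosen with the same limits, and again none passed the test. Dimmer genes such as Angptl1 (-1.16) and Wnt2b (-0.94) fell outside them, as did the brighter Igfbp2 (-0.69), which was higher in WTA. Clec3b, the plasminogen-binding tetranectin, had a log2 value of 7.84 ± 0.43 with streptozotocin and 8.88 ± 0.29 without (SD, n = 2 each). Lum, the collagen-binding proteoglycan lumican, differed by -0.83, with -1.32 in WT2 and -0.34 in WTA. Angpt2, a ligand of Tie2, differed by -0.69, and Il17rd, a membrane antagonist of fibroblast growth factor signalling, by -0.67. The sulfotransferase gene Chst2 differed by -0.65 and the cytokine receptor gene Il31ra by -0.65. Gcnt1, a branching enzyme of O-glycans, differed by -0.56, and its second probe set by -0.22. The Wnt receptor gene Fzd2 differed by -0.54, Clec11a, a secreted growth factor of bone, by -0.53, and the fibroblast growth factor gene Fgf18 by -0.52. With 1 array left out, the direction turned for Angpt2 (-1.89 to 0.50), Gcnt1 (-1.30 to 0.18) and Clec11a (-1.44 to 0.39). Within the cultures Clec11a differed by -0.67 in WT2 and -0.38 in WTA.

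**Figure D1:**
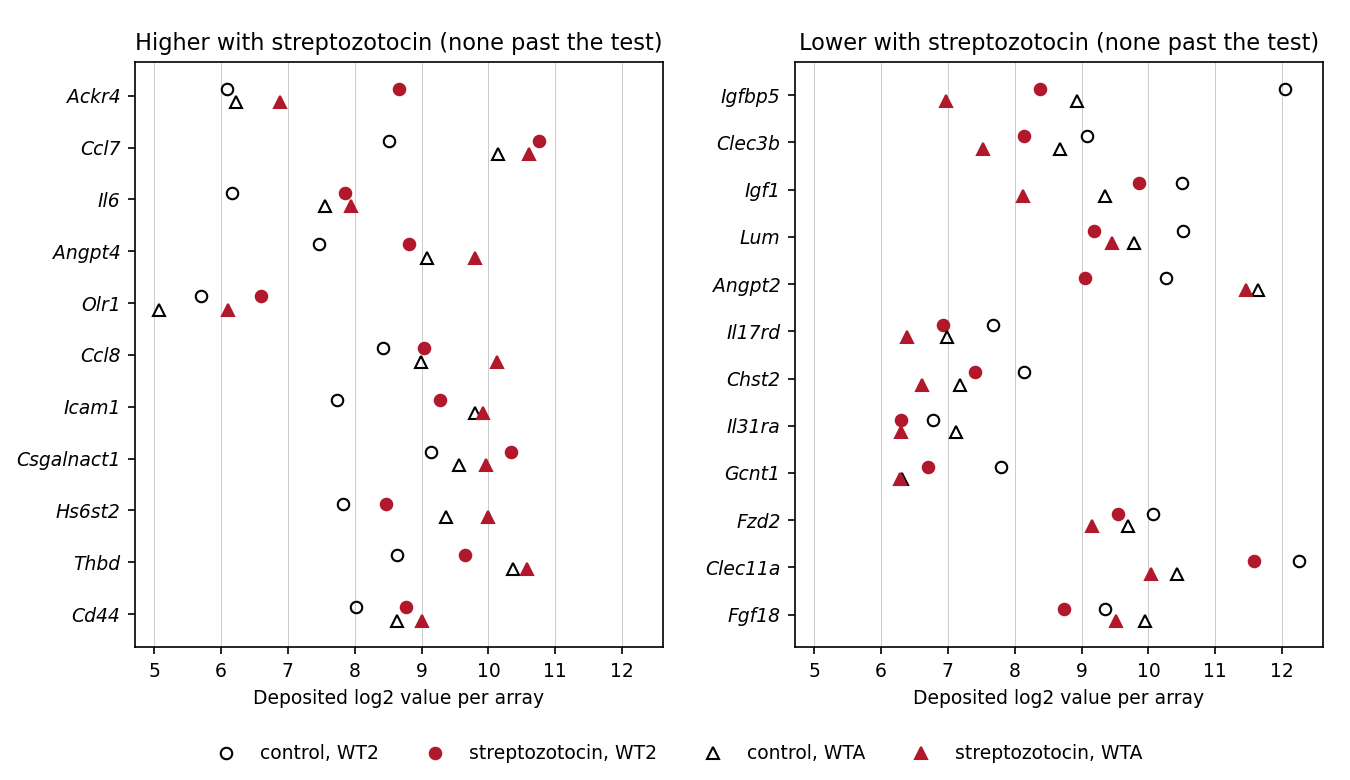
Deposited log2 values per array of 11 of the 12 genes with the largest positive (left) and of the 12 with the largest negative (right) streptozotocin difference among those above the median level that went the same way in both cultures; open symbols are control arrays, filled symbols streptozotocin arrays, circles WT2 and triangles WTA. For Igfbp5 the pairs are -3.67 and -1.95 apart, and no gene shown passed the test.

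In limma's fit without the block, 25 probe sets had an unadjusted p under 0.05, 9 higher and 16 lower with streptozotocin, where 62.3 are expected by chance, and the smallest adjusted p was 1. That fit counts the difference between the cultures as noise (median SE 0.120, against 0.102 with the block). It recovered 3.07% of simulated 1.5-fold changes, so its count of 0 does not show that no gene responds. With the replicate number as a block, which pairs the arrays of a culture, limma found 80 at an unadjusted p under 0.05, 37 higher and 43 lower, and 0 at an adjusted p under 0.05 (smallest 0.536).

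Hexosamine pathway genes make the sugar donor of protein O-GlcNAc, and the cycling enzymes add and remove that sugar. Ogt, which adds it, had a log2 value of 7.21 ± 0.14 with streptozotocin and 7.59 ± 0.10 in control cells (SD, n = 2 each). Its difference was -0.36 in WT2 and -0.40 in WTA, which did not pass the test (limma adjusted p = 1). Oga, which removes O-GlcNAc and whose enzyme streptozotocin is known to inhibit, differed by 0.02. Gfpt1 and Gfpt2, the entry enzymes of the pathway, differed by 0.04 and 0.26, and Gnpda2, a glucosamine-6-phosphate deaminase, by 0.35. Of the 16 measured genes of this list 0 passed the test, over all probe sets or adjusted over the list alone. Their median difference was 0.02 (camera adjusted p = 0.485).

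The lists of glycosaminoglycan and proteoglycan genes had 0 genes past the test. Has2, a hyaluronan synthase, differed by 2.20 in WT2 and -0.50 in WTA. With Cd44 and 4 other genes it formed the hyaluronan list, whose median difference was 0.13 (camera p = 0.0305, adjusted p = 0.265, and p = 0.295 with an estimated correlation). Among the 24 heparan sulfate genes, Ext1, a polymerase of the chain, and Sulf1, an extracellular sulfatase, each differed by 0.46, and the list median was 0.00 (adjusted p = 0.959). The 18 chondroitin and dermatan sulfate genes had a median of -0.06 and the 12 genes of keratan sulfate and other sulfotransferases one of -0.04 (adjusted p = 0.485 and 0.497). Among the 29 proteoglycan core proteins, Gpc3 and Gpc6, which are glypicans of the cell surface, differed by -0.50 and -0.42, and Fmod, fibromodulin, by -0.44. The abundant matrix proteoglycans Bgn (biglycan) and Dcn (decorin) differed by -0.00 and -0.34. The median of that list was -0.02 (adjusted p = 0.810).

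For protein and lipid glycosylation, 0 genes and 0 lists passed the test. The list of O-mannose, O-fucose and O-glucose glycosylation genes had the lowest p among those with a negative direction. Of its 12 genes 8 were lower with streptozotocin in both cultures, with a median of -0.09 (camera p = 0.0263, adjusted p = 0.265, and p = 0.149 with an estimated correlation). Its member Lfng, a Fringe enzyme that modifies Notch receptors, differed by -0.42, and Dag1, dystroglycan, by -0.24. In the N-glycan trimming and branching list, 11 of 18 genes were lower in both cultures and 0 higher in both (median -0.08, adjusted p = 0.485), with Mgat2 at -0.25. Of the 29 O-GalNAc genes 13 were lower in both cultures and 6 higher (median -0.04, camera adjusted p = 0.485). The set test fry, also of limma, gave that list its smallest adjusted p, 0.495. The medians were -0.02 for 20 N-glycan precursor genes and 0.01 for 33 nucleotide sugar genes, among them the UDP-GlcNAc transporter gene Slc35a3 at -0.38 (camera adjusted p = 0.497 and 0.810). They were 0.04 for 19 sialyltransferases and -0.10 for 10 fucosyltransferases (adjusted p = 0.810 and 0.485). For 25 lysosomal genes the median was -0.07, for 7 GPI anchor genes -0.12 and for 10 galectins -0.08 (each adjusted p = 0.485). The 19 glycosphingolipid genes and the 14 mucins had medians of 0.01 and 0.01 (camera adjusted p = 0.951 and 0.651). In both, the mean was below 0 while the median and camera's direction were positive.

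The chemokines gave the smallest list p. Cxcl13, an attractant of B cells, differed by 3.50 in WT2 and -0.17 in WTA, and Cxcl14 by 2.12 and 0.00. For Cxcl13 the control array of WT2 was the odd one, at 4.32 against 7.82, 7.14 and 7.31 in the other arrays. For Cxcl14 it was the streptozotocin array of WT2, at 8.03 against 5.91, 6.60 and 6.60. The median over 29 chemokines was 0.07, the mean 0.26, and 8 were higher and 6 lower in both cultures (camera p = 0.00784, adjusted p = 0.204, and p = 0.151 with an estimated correlation). Without the control array of WT2 camera gave an adjusted p of 0.995, and without the control array of WTA one of 0.0172. The list of 5 adhesion molecules held Icam1, Selp (0.49), a selectin, and Vcam1 (0.22), a ligand of leukocyte integrins, and had a median of 0.22 (adjusted p = 0.485). Among 33 interleukins and tumour necrosis factor ligands the median was 0.03 (adjusted p = 0.485), with Csf1, the macrophage growth factor, at 0.37. Markers of other cell types were measured beside these groups: the median was 0.00 for 27 leukocyte and macrophage markers and 0.08 for 7 endothelial markers (adjusted p = 0.497 and 0.485).

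Of genes tied to bone formation, Bmp2 differed by 0.07 in WT2 and -0.07 in WTA, and Bmp4 by 0.37 and -0.78. Both are bone morphogenetic proteins, and neither passed the test. The median over 38 BMP and TGF-beta ligands and receptors was -0.01 (camera adjusted p = 0.872), with Tgfb3 at -0.37. The 48 growth factors and receptors of the FGF, PDGF, VEGF, IGF and EGF families had a median of -0.03 and a positive camera direction (adjusted p = 0.959). The receptor gene Met differed by 0.54 there and its ligand gene Hgf by 0.51. The 17 Notch pathway genes had a median of -0.06 (adjusted p = 0.485). The list of osteogenic genes had 4 measured members, the housekeeping list 1, and the lists of contractile and DNA damage genes 0, so they were not tested. Runx2, Alpl, Spp1, Bglap, Tnfrsf11b and Acta2 were not among the named probe sets.

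The second comparison set the streptozotocin difference in WT2 beside that in WTA, with 1 array per arm in each culture and no test. There were 6 named genes at least 1.5-fold higher in both cultures, Ackr4, Angpt4, Ccl8, Hs6st2, Olr1 and Klra2, the last of a receptor family with near-identical copies. Another 6 were at least 1.5-fold lower in both, Igfbp5, Clec3b, Igf1, Il17rd, Angptl1 and Wnt2b. With 1 probe set that has no symbol here, these were 7 higher and 6 lower probe sets, against 0.385 and 0.522 for independent lists of the same sizes. That reference takes all probe sets as equally able to move, which dim ones are not. Opposite moves exceeded it too (3 against 1.21), so the excess does not measure a shared response. Over all probe sets, 51.0% had the same sign in both cultures. Klra2, Angptl1 and Wnt2b lay outside the rule for named genes and were picked after their values were seen. The differences were wider in WT2, with an SD over probe sets of 0.402 (95% bootstrap interval 0.351 to 0.456), than in WTA, with 0.220 (0.2003 to 0.241). These intervals describe probe sets within 1 pair of arrays per culture, and do not show that another pair would differ in this way. The Pearson correlation of the 2 sets of differences across probe sets, which are not independent replicates, was 0.151 (0.00762 to 0.300), and Spearman's rho was 0.0872. In WT2, 60 probe sets were at least 1.5-fold higher and 31 lower, and in WTA 8 and 21. The control array of WT2 had the lowest correlations with the arrays of WTA, 0.977 and 0.982, while the arrays of WTA correlated at 0.997 with each other.

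**Figure D2:**
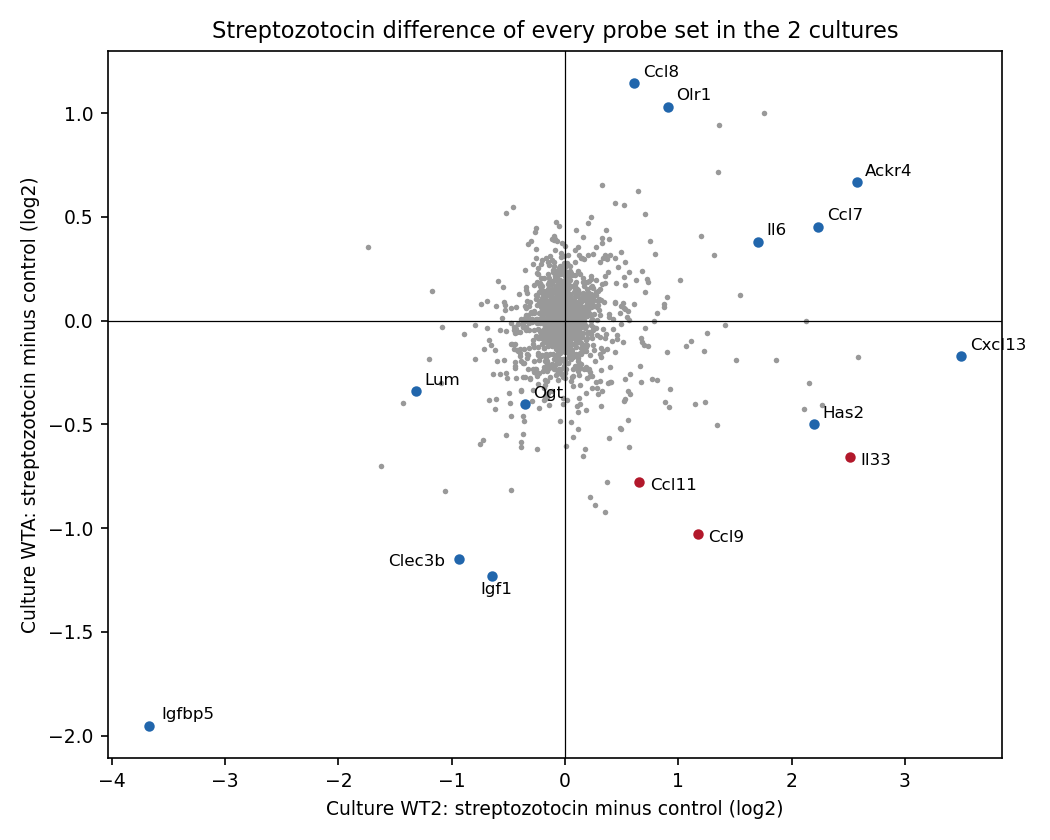
Streptozotocin minus control (log2) in culture WT2 (horizontal) and in culture WTA (vertical), 1 point per probe set, with named genes in blue and, in red, the 3 genes that were at least 1.5-fold higher in WT2 and lower in WTA. The horizontal spread (SD 0.402) is wider than the vertical spread (SD 0.220), and Igfbp5 lies farthest below 0 in both.

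The third comparison set the cultures against each other, in a fit with treatment and culture. Esm1, a proteoglycan that endothelial cells secrete, was higher in WTA than in WT2 by 4.93 on the log2 scale (SE 0.10, limma adjusted p = 0.00304), and its second probe set by 2.93. The WT2 values, 3.99 and 4.48 for the first and 2.81 and 3.32 for the second, lay near or below the lower quartile of those arrays (4.39). Background holds part of such values, so the sizes of both differences are uncertain. St6gal1, which adds sialic acid to N-glycans, was higher in WTA by 1.69, Bmp8a, a bone morphogenetic protein, by 1.69, and the neurotrophin gene Bdnf by 1.63. Klra4, of the same receptor family as Klra2, was higher by 2.52, which is uncertain because its copies are alike and its WT2 values of 2.81 and 3.06 are near the lowest measured. In the other direction, WTA minus WT2 was -2.34 for Mdk, the heparin-binding growth factor midkine, and -1.98 for Gdf10, a relative of the bone morphogenetic proteins. It was -1.88 for Gfra1, a co-receptor of the glial-derived neurotrophic factor, -1.69 for Clec11a, and -1.24 for Il15ra, the interleukin 15 receptor.

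In all, limma found 28 probe sets at an adjusted p under 0.05, 18 higher and 10 lower in WTA, and 210 at an unadjusted p under 0.05. The 26 with a symbol stand for 24 genes, 14 higher and 10 lower. Among them, the glycogenes Hs6st2 (1.54), C1galt1 (0.97), which makes the core of most O-glycans, Hs3st1 (1.00) and Gal3st2 (0.93) were higher in WTA. Fgf10 and its receptor gene Fgfr2 were lower in WTA (-1.24 and -1.05), as were Fzd1 (-1.15) and Cd34 (-1.07). Hs3st1, Fgf10, Fgfr2 and Fzd1 were named outside the rule, after their values were seen. The comparison describes 2 cultures, and its p-values hold no spread between cell samples of a kind. The count depends on the setting: limma called 37 probe sets after median centring, 8 after quantile normalization and 2 of the 623 above the median level. In a fit with the culture alone, 0 were called when either array of WTA was left out.

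**Figure D3:**
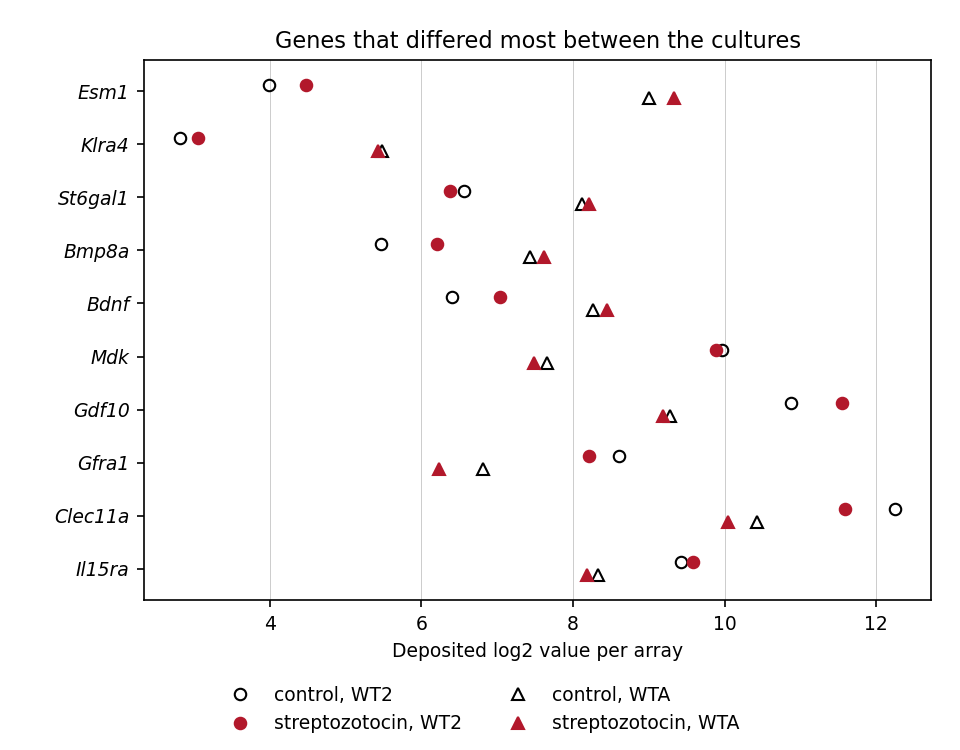
Deposited log2 values per array of the 5 genes with the largest culture difference in each direction among those past the test; open symbols are control arrays, filled symbols streptozotocin arrays, circles WT2 and triangles WTA. The Esm1 arrays of WTA lie 4.93 above those of WT2 on average, and for every gene shown the arrays of the cultures do not overlap.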

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

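The test of excess variance and the test of endothelial markers were chosen after the results were seen. The matched probe sets were reduced from 5 to 2 for each ubiquitous one after a first run, for a closer level (9.87 against 9.95, from 9.25). With 5, the share of excess variance was 0.0941 and the ratio for the culture difference 0.369. For 3 chemokine and cytokine genes the streptozotocin difference had opposite signs in the cultures, each by at least 1.5-fold, a size set after the data were seen. With 1 array per arm in each culture the differences between cultures were not tested. Il33, an alarm cytokine, differed by 2.52 in WT2 and -0.66 in WTA. Its WT2 control value was 6.70, against 9.22, 8.83 and 9.49 in the other arrays. The chemokine genes Ccl9 and Ccl11 differed by 1.17 and 0.66 in WT2 and by -1.03 and -0.78 in WTA. The WT2 control array was the lowest for Ccl9 too, at 5.53, but not for Ccl11. If all probe sets were equally able to move, independent lists of the same sizes would give 1.21 probe sets with opposite signs.

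These 3 genes belong to a wider pattern, the larger streptozotocin differences in WT2 than in WTA (ratio of the SDs 1.83, interval over probe sets 1.62 to 2.05). If array quality or normalization of the WT2 pair were the cause, genes that every cell uses should show it too. Over 67 probe sets of 65 such genes the ratio was 1.22 (interval 0.952 to 1.55), against 1.56 in 134 other probe sets of matched level. The excess variance of WT2 was 0.101 of that in the others (interval -0.0362 to 0.630), which argues against noise of equal size in all probe sets as the whole cause. The ubiquitous genes varied less in WTA too (SD 0.164 against 0.305), so noise that scales with a gene's spread would also give a low share. The interval of the ratio reaches close to 1.56, so such noise stays open. More leukocytes in the WT2 streptozotocin culture stay open: the median WT2 difference of 27 leukocyte markers was -0.00073. The 3 above the array median had a median of -0.03, and 0 of them was higher by 0.5, but their spread (SD 0.32) reaches past the bound of 0.25 set in advance. By that bound alone the markers would count against leukocytes, and the demand on the spread was added after the values were seen. A different response of the cultures, or a deviation of the WT2 control array alone, may also be the source, and neither was tested.

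The differences between WTA and WT2 were weighed in the same way. In the ubiquitous genes the SD of the culture difference was 0.354 times that in the matched others (interval 0.277 to 0.474), which argues against array noise of equal size in all probe sets as the whole cause. These genes also varied less with streptozotocin in WTA (SD 0.164 against 0.305), so noise that scales with a gene's spread stays open here too. Endothelial cells in WTA are another candidate source, since Esm1 is an endothelial gene. The 6 other measured endothelial markers had a median difference of 0.10, with Emcn at 1.22, Selp at 0.79, Pecam1 at 0.15, Madcam1 at 0.05, Sele at 0.05 and Icam2 at -0.19. By the rule written for this test, such a median, with 1 of the 6 higher by 1 or more, would count against endothelial cells. A further demand, that at least 5 of the markers lie above the array median, is not in that rule. As 2 of the 6 lay above it, endothelial cells stay open, as does the origin of the cells, which was not tested.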

How the results depend on the processing

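The fits of the culture alone, their versions without an array, the fit on probe sets without the suffixes s, x or a, and the other settings for the per-culture differences were chosen after the data were seen. The count of 0 probe sets past the test of streptozotocin held under all 14 alternatives, left-out arrays included, where a group of 1 array was assumed to vary like the other group. Among these alternatives, the added limit of 1.5-fold could not raise a count of 0. The looser threshold used the main fit, whose adjusted p-values all lay above it, so it could not differ either. With the replicate block the smallest adjusted p was 0.536, 80 probe sets instead of 25 had an unadjusted p under 0.05, and the block changed no call of a probe set or list. The count of lists was 0 under 11 of 12 alternatives. Over the 4 left-out arrays it was 0 to 2, with the chemokines' adjusted p between 0.0172 and 0.995 and that of the hyaluronan list between 0.0268 and 0.995. The lowest value of both lists came without the control array of WTA, where the control array of WT2 is the only control left. The contrast then also holds the culture difference. Cxcl13 (4.32) and Has2 (4.94) had their lowest values in that remaining control array. Over the other alternatives the chemokines' adjusted p lay between 0.0930 and 0.892.

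The culture difference depended most on the setting. From 28, the count of probe sets went to 37 with median centring, to 8 with quantile normalization, to 2 among the brighter probe sets and to 13 with the culture alone in the fit, all of these 8, 2 and 13 among the 28. With the culture alone it was between 0 and 18 when an array was left out, 0 without either array of WTA. Of the 28, 21 were among the 623 probe sets that the dim filter leaves, and the cause was not tested. A left-out array under the fit with treatment and culture leaves no residual degrees of freedom, so that setting, fixed before the data were examined, was not run, and the pseudocount did not apply to log2 values. The ratio of the SDs stayed between 1.83 and 1.91, and r between 0.151 and 0.167.

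Of 51 genes named for their streptozotocin difference 0 passed under any alternative. Bgn was at 0.010 after median centring and 0.024 after quantile normalization, and Gfpt1 at -0.015 after the latter. With each array left out in turn, 42 of the 51 differences moved by over 1.5 times or changed sign, and 12 changed sign. A left-out array unbalances the cultures, so these values also hold the culture difference. The differences ranged from -1.89 to 0.50 for Angpt2, -0.028 to 0.025 for Bgn, -1.11 to 0.70 for Bmp4, -0.073 to 0.11 for Oga and -0.20 to 1.87 for Icam1. They ranged from -0.14 to 1.41 for Hs6st2, -0.27 to 1.48 for Thbd, -1.30 to 0.18 for Gcnt1 and -1.44 to 0.39 for Clec11a. The ranges were -0.069 to 1.77 for Has2, -0.46 to 2.32 for Il33 and -0.028 to 0.10 for Gfpt1. Probe sets near the lowest log2 values hold little signal over background, which limits what dim genes can show.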

Other observations

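The gene families in the next sentences were picked after the data were seen, while the test of Oga was written before its value was looked at. Of 12 insulin-like growth factors, their receptors and binding proteins, 5 were lower and 1 was higher with streptozotocin in both cultures, with a median of -0.13. Camera did not call them (p = 0.0903, adjusted p = 0.451 over 5 families, and p = 0.269 with an estimated correlation). Beside Igfbp5 and Igf1 the family held Igfbp2, which differed by -1.74 in WT2 and 0.35 in WTA, and Igf2, by 0.92 and -0.42. Among 28 Wnt ligands and Frizzled receptors, Wnt2b differed by -0.94 and came closest to passing without the block (limma adjusted p = 1). Wnt4 differed by 2.15 in WT2 and -0.30 in WTA, and the family by a median of -0.02 (camera adjusted p = 0.503). Among 9 angiopoietins and related proteins, 3 were higher and 4 lower in both cultures (median -0.25, camera adjusted p = 0.503).

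The culture difference was also run over the 26 lists after the data were seen, and 0 passed. The endothelial markers, which include Esm1, were closest (camera p = 0.00302, adjusted p = 0.0786, and p = 0.226 with an estimated correlation), followed by the fucosyltransferases, lower in WTA (p = 0.00687, adjusted p = 0.0894, and p = 0.216 with an estimated correlation).

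Ogt was lower with streptozotocin in both cultures, by -0.36 and -0.40, without passing the test. A candidate explanation is feedback on the O-GlcNAc cycling enzymes, since streptozotocin inhibits the O-GlcNAcase. Such feedback was taken to raise Oga by at least 0.2 in both cultures. Oga differed by -0.019 in WT2 and 0.06 in WTA, below that size in both. By the rule written in advance this counts against the feedback. A demand that the 95% interval also exclude 0.2 was added after the value was seen. The mean difference of 0.018 had an interval from -0.31 to 0.34, which includes 0.2, so the hypothesis is left open. Protein O-GlcNAc levels were not measured here.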
